A study of Homo sapiens and Mus musculus with 6 samples.

How the data were processed

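Capsule tissue around silicone implants was profiled by droplet single-cell RNA sequencing on the 10x Genomics platform, with antibody hashtags that mark the cells of different samples inside 1 library. Per the labels, 2 libraries came from mice and 4 from human capsules, and each library held either ADM-adjacent or native (mouse: non-ADM control) capsule. ADM is taken here as acellular dermal matrix, a sheet of decellularised skin used to cover implants; the labels give only the abbreviation. Per the labels' protocols, C57BL/6J mice received 0.2 mL PDMS (silicone) implants on the back, capsules were harvested on postoperative day 28, and tissue was digested with collagenases II and IV. Some hashed samples were sorted to be lineage-negative (Lin-), with antibodies against Tie2, CD45, CD31, CD324, CD326 and Ter119 in mouse, and the others were left unsorted.

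Each matrix held the deposited UMI counts of genes and hashtags per droplet barcode, made with Cell Ranger per the file headers, version 6.0.0 for mouse and human set 2 and version 4.0.0 for human set 1. The genome builds were mm10 and GRCh38, and Seurat was named without a version, per the submitters' processing notes. Every matrix held whole numbers of raw counts, and no normalization had been applied. The alignment settings and any correction for free RNA were not given in the sources used here. The matrices had 31053 mouse or 33538 human genes. They held 4582 and 7365 barcodes for mouse ADM and native, 453 and 1101 for human set 1, and 903 and 1947 for human set 2.

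Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept. They were assigned to hashtags with HTODemux of Seurat 5.3.0 (quantile 0.99, seed 42). The tags of each library came from the labels. In the order ADM then native, singlets made up 61.2% and 54.0% of mouse cells, 73.4% and 21.3% of human set 1, and 64.0% and 63.8% of human set 2. The native library of human set 1 therefore lay under the 50% of cells that had been set as the minimum, with 403 of 766 cells called doublets. Below that minimum the plan was to take each library as 1 sample and run no test. This library was nevertheless kept in the human macrophage fit and in the test of shares, a departure from the plan. The counts of genes in human macrophages and fibroblasts are also given without it. Hashtags missed fibroblasts more often than macrophages: no tag was assigned to 47.7% and 43.4% of fibroblasts in the mouse ADM and native libraries, against 8.44% and 9.00% of macrophages.

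Cells of each species were normalized to 10000 UMIs, log-transformed and clustered with scanpy 1.11.5 (2000 variable genes chosen per library, 30 principal components, 15 neighbours) and leidenalg 0.10.2 at resolution 1, without any alignment between libraries. Clusters were named from 15 marker sets, by the class with the largest fraction of its markers detected. Where more markers of another class were among a cluster's 10 leading genes, it took that class's name. The human dendritic cluster was renamed in this way from macrophage, with 4 of 8 dendritic markers and 6 macrophage markers detected. The naming rule was changed after the data were seen: a class needed at least 3 of its markers detected in at least 25% of the cluster's cells, and a cluster that fitted 2 classes, or had low counts and no leading marker, stayed unnamed. Unnamed cells made up 5.63% and 6.84% of the mouse libraries, 5.65% and 6.53% of human set 1, and 5.28% and 2.36% of human set 2. Scrublet found at most 1.32% doublets in any library, and its calls were used in an alternative only.

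Counts were summed per hashed sample and class (at least 10 cells), and ADM was compared with native by the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with TMM factors, filterByExpr, Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Each "adjusted p" of a gene is from this test unless another is named. The SE of a gene is an approximate standard error of its log2 fold change. It is the absolute fold change divided by the square root of the test's F statistic, and is least reliable at counts near 0. Mouse fibroblasts came from the Lin- hashed samples and macrophages from the unsorted ones. Human fibroblast counts joined hashtags that the protocol calls the same biological replicate, and both human fits had the library set as a term. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. Shares of cells were compared between unsorted hashed samples of at least 20 cells by exact two-sided permutation, within library sets for human. The design, the 19 gene lists, the marker sets and the named-gene rule were fixed before the data were examined, and so were most alternatives. The alternatives covered tool, normalization, filters, hashtag assignment, clustering, doublets, a replicate block and samples left out.

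The genes named follow a rule. Spp1 was always named. In each fit, of genes with adjusted p under 0.05 and average log2 CPM of at least 5, up to 12 of the largest positive and 12 of the largest negative fold changes could be named, and of each list up to 4 members with the smallest p. Where fewer than 5 genes passed, the 10 with the smallest p could be named. Mitochondrial, ribosomal, immunoglobulin and T cell receptor variable, hemoglobin, predicted and sex-chromosome marker genes were left out of it; ribosomal proteins appear only as a group.

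The procedure was tested on simulated data drawn from each fit's own means and library sizes, with 200 genes changed. Genes changed 4-fold were recovered at 96% in the mouse fibroblast design, 77% in mouse macrophages, 86% in human fibroblasts and 86% in human macrophages. For 2-fold changes the recovery was 62%, 8%, 31% and 6%, and false calls made up 6.51%, 9.57%, 4.1% and 6.12% of calls. Intervals on shares and UMIs per cell are exact 95% intervals and cover counting error only. A mouse genome annotation was not used here, so coordinates are given for the human gene only.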

Results

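The data were single-cell transcriptomes of capsule, the fibrous tissue that forms around an implant as a foreign body response. In mouse, 1 library held ADM-adjacent capsule with 6 hashed samples (4 Lin-, 2 unsorted) and 1 held native capsule with 7 (4 Lin-, 3 unsorted). The mouse protocol states n = 6 per condition but does not say that each hashtag marks a separate animal. In human, 2 library sets each held an ADM library and a native one. The libraries of set 1 carried 8 hashed samples each (5 Lin-, 3 unsorted), and those of set 2 carried 5 each, all unsorted. The labels do not say whether ADM and native samples shared donors.

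The mouse ADM library had 28077850 gene UMIs and 4049 cells after filtering, with a median of 3955 UMIs per cell. Its native counterpart had 35911396 UMIs, 6214 cells and a median of 3623.5. Human set 1 had 2968564 UMIs in its ADM library and 5568396 UMIs in its native one, which had 766 cells. Human set 2 had 7991089 UMIs in 644 ADM cells and 15806240 UMIs in 1571 native cells. Fibroblasts and macrophages were the main classes in mouse, at 33.4% and 38.0% of ADM cells and 43.5% and 27.5% of native cells. In human set 2 they made up 39.8% and 28.7% of ADM cells and 50.4% and 23.9% of native cells. T and NK cells led human set 1, with 39.2% of ADM and 58.0% of native cells.

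Every comparison below set ADM against native capsule. Each condition was a single library in mouse and within each human set, so a difference between conditions cannot be separated from a difference between libraries, and the p-values measure only the spread between hashed samples. Positive log2 fold changes mean higher next to ADM.

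The series title names osteopontin, the secreted phosphoprotein encoded by Spp1 (ENSMUSG00000029304) in mouse and SPP1 (ENSG00000118785; GRCh38 chromosome 4, 87975650 to 87983426, plus strand, a protein-coding gene in GENCODE 29) in human. The first question was which cells carried its mRNA and whether its level differed with ADM. Macrophages held most of it: 64.7% of Spp1 UMIs in the mouse ADM library and 66.9% in the native one. Mouse fibroblasts held 30.3% and 20.6%. In human libraries macrophages held from 91.6% to 99.8% of SPP1 UMIs.

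Spp1 in mouse fibroblasts averaged 399.5 ± 293 CPM next to ADM and 119 ± 79.5 CPM in native capsule (SD, n = 4 and 4 hashed samples), a log2 fold change of 1.66 (SE 0.54). It did not pass the test (edgeR adjusted p = 0.148, and between 0.0188 and 0.855 over the alternatives). With tags assigned where 1 took at least 80% of a cell's tag UMIs the value was 0.60. The ADM level lay above every native sample in 2 of 4 hashed samples. Over all fibroblasts of the 2 libraries, hash doublets included, it was 701 CPM against 217 CPM, and without those doublets 717 against 223 CPM. In mouse macrophages Spp1 was 2507 ± 227 CPM (n = 2) against 3232 ± 2410 CPM (n = 3), a log2 fold change of -0.37 (SE 0.63, edgeR adjusted p = 0.969). In Lin- macrophages of the same libraries, a comparison added after the results were seen, it was 0.97 (SE 0.51, n = 4 and 4, edgeR adjusted p = 0.760). The direction in macrophages turned to 0.28 with a replicate block and to 0.27 without native hashed sample 5. The difference between the effects in unsorted macrophages and in Lin- fibroblasts was -2.01 (SE 0.96, edgeR adjusted p = 0.637).

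In human macrophages SPP1 averaged 16718 ± 12418 CPM in 5 ADM samples and 2403 ± 3219 CPM in 4 native samples. The log2 fold change was 3.68 (SE 1.07) and did not pass the test (edgeR adjusted p = 0.182, and between 1.54e-10 and 0.624 over the alternatives). By DESeq2 it was 3.65 and passed. Compared across both sets, SPP1 was above every native sample in 3 of 5 ADM samples. Within sets the samples did not overlap. In set 2 they ran from 5642 to 31551 CPM in ADM and from 158 to 2285 CPM in native capsule. In set 1 the ADM sample had 12305 CPM and the native one 6994 CPM. Over all macrophages of set 2 it was 19529 CPM in the ADM library and 389.5 CPM in the native one, and in set 1 it was 19632 CPM against 5227 CPM (10340 against 6112 CPM without hash doublets). The set difference in this effect was 3.59 (SE 2.01, edgeR adjusted p = 0.529), with 1 sample per condition in set 1, assumed to vary like those of set 2.

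**Figure D1:**
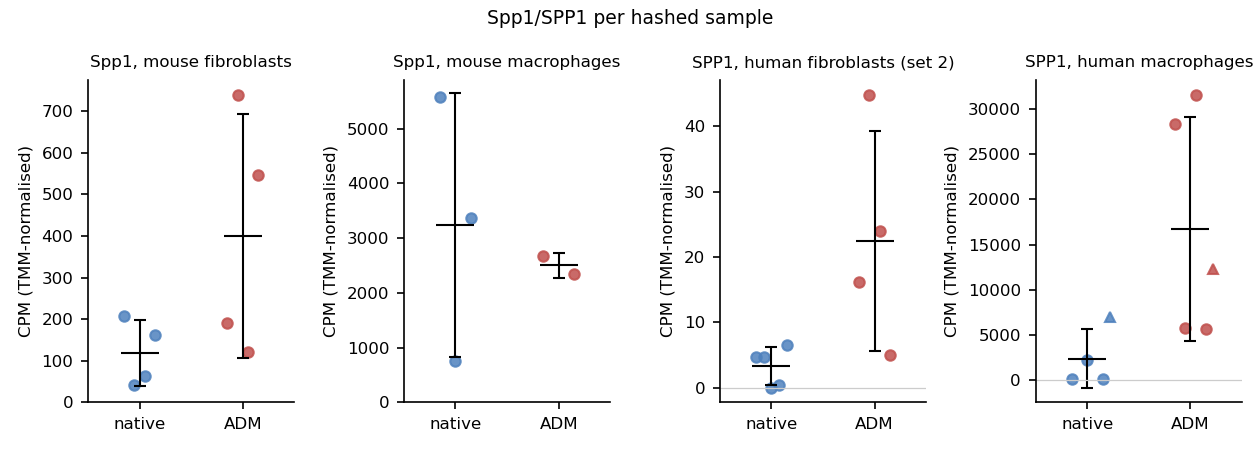
Spp1 or SPP1 level in CPM per hashed sample in fibroblasts and macrophages of mouse and human capsule, ADM against native. Triangles are human set 1, circles are human set 2 or mouse, and bars are mean ± SD; human macrophages next to ADM lay between 5642 and 31551 CPM.

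Mouse fibroblasts were compared to ask how the resident matrix-producing cells differ next to ADM. Fibroblasts of the ADM library had more mRNA for several matrix and matrix-regulating proteins. Col6a5, a collagen VI chain, rose from 85.4 ± 17.2 to 398 ± 226 CPM (log2 fold change 2.29, SE 0.36, edgeR adjusted p = 0.00728; n = 4 and 4). Tnn (tenascin-W, 1.77, SE 0.27), Grem1 (an antagonist of bone morphogenetic proteins, 1.65, SE 0.31), Col7a1 (the anchoring fibril collagen, 1.37, SE 0.30) and Col12a1 (a fibril-associated collagen, 1.13, SE 0.15) rose as well, with edgeR adjusted p from 0.00378 to 0.0387. With tags assigned where 1 took at least 80% of a cell's tag UMIs the direction turned for Grem1 (-0.10), Col7a1 (-0.42) and Ptk7 (-0.12). Genes that fell included Dmkn (dermokine, a secreted skin protein, -3.18, SE 0.51), Sbsn (suprabasin, -1.85, SE 0.29) and Akr1c18 (a steroid dehydrogenase, -3.11, SE 0.58), with edgeR adjusted p from 0.00728 to 0.016. In all, 168 of 9304 genes passed, 37 higher and 131 lower next to ADM (edgeR quasi-likelihood test), and 1364 genes had an unadjusted p under 0.05.

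Other genes that rose were Igfbp2 (1.85), Hmox1 (heme oxygenase 1, 1.52), Uck2 (1.34), Slc7a2 (a transporter of cationic amino acids, 1.30), Ptk7 (1.05) and Nrep (1.03), with edgeR adjusted p from 0.00219 to 0.0448. Each gene named so far that rose exceeded every native sample in 4 of 4 ADM samples, except Col7a1, which did so in 3 of 4. Other genes that fell were Bckdhb (-1.73), Ifi27l2a (-1.47), Mustn1 (-1.42), Mpp6 (-1.33), Ildr2 (-1.26), Wnt2 (-1.23), Pcsk6 (-1.22), Efhd1 (-1.19) and Polr2j (-1.18), with edgeR adjusted p from 0.00219 to 0.0287. Each gene named so far that fell lay below every native sample in 4 of 4 ADM samples, except Akr1c18, with 2 of 4.

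**Figure D2:**
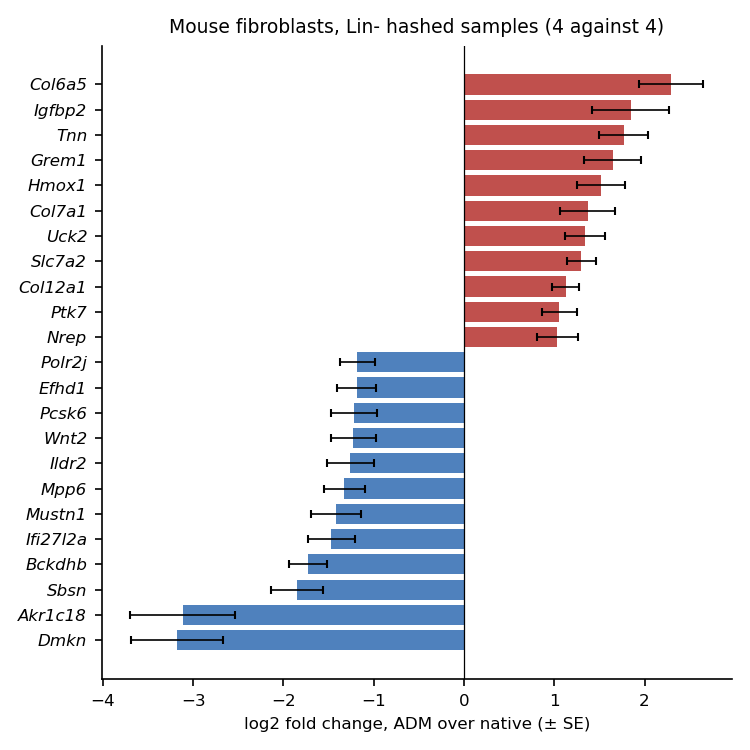
Log2 fold change (ADM over native, bar ± SE) of the named genes that passed in mouse fibroblasts of the Lin- hashed samples (n = 4 and 4). Values run from -3.18 for Dmkn (9.19 against 67.6 CPM) to 2.29 for Col6a5.

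The list of adventitial fibroblast genes, which mark the perivascular Pi16-positive state, was lower next to ADM (camera adjusted p = 3.02e-07; adjusted p = 0.161 with an estimated correlation). Of its 9 genes 2 fell, Pi16 (-1.05, SE 0.16) and Anxa3 (-1.10, SE 0.21), with edgeR adjusted p of 0.00728 and 0.018, and 6 passed when adjusted over the list alone, among them Cd34 (-0.49) and Clec3b (-0.63). Complement genes had negative fold changes in 8 of 8 (median -0.546; camera adjusted p = 0.000217; adjusted p = 0.283 with an estimated correlation). Serping1, the C1 inhibitor, fell by 0.79 (SE 0.16, edgeR adjusted p = 0.0254), and with C4b (-0.78) it made 2 genes adjusted over the list alone. Pericyte markers were lower too (camera adjusted p = 0.000949; adjusted p = 0.161 with an estimated correlation), and the pericyte and smooth muscle class itself held 1.95% of ADM and 4.44% of native cells. Kcnj8, a potassium channel subunit, fell by 2.11 (SE 0.35, edgeR adjusted p = 0.00931), and its partner Abcc9 had -0.82; these 2 of 3 passed when adjusted over the list alone. By fry the adventitial and pericyte lists kept an adjusted p of 0.0444 each.

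The collagen and matrix list was higher (camera adjusted p = 0.000949; adjusted p = 0.283 with an estimated correlation). Of 19 genes 1 passed, Col12a1, and 5 did when adjusted over the list alone, among them Col6a3 (0.49), Postn (periostin, 0.88) and Tnc (tenascin-C, 1.05). Matrix proteases and inhibitors were higher (camera adjusted p = 0.00472; adjusted p = 0.249 with an estimated correlation), and 1 of 13 rose, the membrane collagenase Mmp14 (0.83, SE 0.16, edgeR adjusted p = 0.0166), with 3 adjusted over the list alone, Mmp11 (0.83) among them. Hypoxia and glycolysis genes were positive in 12 of 12 (median 0.298; camera adjusted p = 0.000579; adjusted p = 0.283 with an estimated correlation). None of these passed and 4 did when adjusted over the list alone, including Ndrg1 (0.71) and Pgk1 (0.60, but -0.14 with the 80% tag assignment). Contractile genes (camera adjusted p = 0.0172) and TGF-beta response genes (camera adjusted p = 0.0214) were higher with 0 of 10 and 0 of 11 passing, and each had an adjusted p = 0.283 with an estimated correlation. Adjusted over the list alone, 0 contractile genes and 1 TGF-beta response gene passed, Lrrc15 (0.96, SE 0.26). Zyx (-0.75, edgeR adjusted p = 0.0103) and Ccl4 (-1.51, edgeR adjusted p = 0.0393, below every native sample in 1 of 4 ADM samples) fell although the mechanosensitive and inflammatory lists they belong to were not called (camera adjusted p = 0.852 and 0.871). Osteopontin receptor genes were not called either (camera adjusted p = 0.871), and interferon genes were negative in 12 of 12 without a call (camera adjusted p = 0.18).

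Dissociation stress genes, induced when tissue is digested, moved with the condition: 14 of 14 were positive (median 0.657; camera adjusted p = 4.12e-11; adjusted p = 0.161 with an estimated correlation). Egr1 (0.79, SE 0.15) and Junb (0.95, SE 0.19) rose, with edgeR adjusted p of 0.0168 and 0.021, Dusp1 had 0.66, and 11 passed when adjusted over the list alone. Ribosomal protein genes made up 40 of the 131 lower genes, and 82 of the 89 tested were negative (78 with library size scaling). They took 8.41% ± 0.69 of UMIs in ADM fibroblasts and 11.3% ± 0.74 in native ones (SD, n = 4 and 4), and in macrophages 9.99% and 9.88%. Fibroblast clusters differed in share: cluster 12, whose leading markers include Akr1c18, Efhd1, Pcsk6 and Sbsn, held 17.3% of ADM and 32.6% of native fibroblasts, and cluster 6, with Tnn and Grem1, held 15.2% and 8.16%. Immune classes made up 58.3% of cells in the Lin- hashed samples of the ADM library and 55.8% of those in the native one. Without native hashed sample 4 the count of 168 became 41, and with tags assigned where 1 took at least 80% of a cell's tag UMIs it was 121, of which 19 were among the 168.

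Mouse macrophages of unsorted samples were compared to ask how the phagocytes at the capsule differ with ADM. No gene passed: 0 of 8906 by edgeR, with 599 at an unadjusted p under 0.05 (445.3 by chance) and 27 by DESeq2 (n = 2 and 3). The genes with the smallest p included Fxyd2 (-2.11, SE 0.25) and Hp (haptoglobin, -2.46, SE 0.31), each with an edgeR adjusted p of 0.153. Ltc4s (leukotriene C4 synthase) had -2.09 at 0.293, and Vsig8 (2.58), Ptgr1 (2.26), Fam198b (1.56), Cdh1 (E-cadherin, 4.86), Serpinb6b (2.84), Cav1 (-1.55) and Gngt2 (-1.33) had 0.306 each by edgeR. Each of these lay beyond every native sample in both ADM samples. They were picked by smallest p from 8906 genes, so this separation largely follows from the choice and adds no support.

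Several lists moved, all of them lost with an estimated correlation. Lipid-associated macrophage genes were higher, positive in 13 of 15 (median 0.53; camera adjusted p = 1.23e-07; adjusted p = 0.422 with an estimated correlation). Ctsl (a lysosomal protease) was 2871 ± 125 against 1138 ± 404 CPM, Cd36 (a lipid scavenger receptor) 2985 ± 546 against 1296 ± 511 CPM and Gpnmb 1415 ± 394 against 381 ± 244 CPM; with Plin2 (a lipid droplet coat protein, 0.84) these were the 4 that passed when adjusted over the list alone. Proliferation genes were positive in 13 of 13 (median 1.05; camera adjusted p = 3.2e-10; adjusted p = 0.422 with an estimated correlation), and 4 passed when adjusted over the list alone, Cdk1 (2.69, SE 0.54) and Ccnb1 (4.49, SE 0.94) among them. Giant cell fusion genes were called higher (camera adjusted p = 0.0329; adjusted p = 0.422 with an estimated correlation), though only 5 of 9 were positive and 4 negative (median 0.205). Dcstamp was at 1.06, and 0 passed when adjusted over the list alone. Inflammatory cytokines were lower in 12 of 14 (camera adjusted p = 0.000895; adjusted p = 0.44 with an estimated correlation). Adjusted over the list alone, 3 were lower, Ccl3 (-1.66), Ccl4 (-1.71) and Tnf (-2.07), and 1 was higher, Ccl8 (3.21). Interferon response genes were lower in 10 of 12, Bst2 at -1.04 (camera adjusted p = 0.000895; adjusted p = 0.44 with an estimated correlation), with 0 adjusted over the list alone.

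Fibroblast transcripts were lower in ADM macrophages, in the same unsorted samples where fibroblasts were 11.98% of ADM and 40.2% of native cells, so doublets or free RNA were not excluded. The collagen list was negative in 13 of 13 (camera adjusted p = 3.2e-10; adjusted p = 0.422 with an estimated correlation) and 6 passed when adjusted over the list alone, including Sparc (-1.01) and Col3a1 (-1.06). Fibroblast markers, which share 4 genes with it, were negative in 8 of 8 (camera adjusted p = 0.000155; adjusted p = 0.422 with an estimated correlation), with 4 adjusted over the list alone, and adventitial genes were lower with 2 (camera adjusted p = 0.00156; adjusted p = 0.422 with an estimated correlation). Dissociation stress genes were lower in 12 of 14, opposite to fibroblasts (median -0.549; camera adjusted p = 0.00127; adjusted p = 0.422 with an estimated correlation), Dnajb1 at -1.12, with 0 adjusted over the list alone. Among osteopontin receptors Itgb3 (integrin beta 3) had 4.71 (SE 0.90, edgeR adjusted p = 0.306) and alone passed when adjusted over the list alone, while the list was not called (camera adjusted p = 0.263, with a median of -0.372 and a mean of 0.256). The macrophages sat in different clusters: clusters 1 and 11 held 26.9% and 25.2% of ADM cells against 2.61% and 4.87% of native cells, and cluster 10 held 13.7% against 45.7%. Median UMIs per macrophage were 4914.5 and 3327.

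Human macrophages of unsorted samples answered the same question in patients' capsules. CHI3L1, a secreted chitinase-like protein, rose from 15.2 ± 27.7 to 664 ± 322 CPM (5.98, SE 1.00), TM4SF19 by 6.03 (SE 1.04), PLIN2, the lipid droplet coat protein, from 102 ± 39.0 to 385 ± 174 CPM (1.98, SE 0.33) and TFRC, the transferrin receptor, by 1.86 (SE 0.31), each with an edgeR adjusted p of 0.0473. The monocyte-attracting chemokine CCL13 fell from 292 ± 184 to 16.8 ± 18.1 CPM (-4.02, SE 0.47, edgeR adjusted p = 0.00521). LILRB5 (-2.96, SE 0.51), PRSS23 (-2.72, SE 0.44) and the lipid transporter family gene ABCA6 (-1.93, SE 0.33) fell with an edgeR adjusted p of 0.0473. These were the 8 of 6715 genes that passed, 4 higher and 4 lower (n = 5 and 4), with 685 at an unadjusted p under 0.05. Over the alternatives other than single samples left out, the count ran from 0 without a set term to 310 without a count filter. Compared across both sets, TM4SF19, CHI3L1 and PLIN2 were above every native sample in 5 of 5 ADM samples and TFRC in 4 of 5. CCL13 and PRSS23 lay below in 5 of 5, LILRB5 in 4 of 5 and ABCA6 in 1 of 5. These counts ignore the set term of the fit, so an overlap in them may come from a difference between sets.

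Of 16 lipid-associated macrophage genes 15 were positive (median 1.82; camera adjusted p = 1.74e-14; adjusted p = 0.112 with an estimated correlation); PLIN2 passed over all genes and 12 when adjusted over the list alone. These included TREM2 (a lipid-sensing receptor, 1.92, SE 0.35), LIPA (lysosomal acid lipase, 2.37, SE 0.44) and LPL (lipoprotein lipase, 3.04, SE 0.74), with edgeR adjusted p of 0.0526, 0.0526 and 0.105. The lipid and adipocyte list, which shares 5 genes with it, was higher as well (camera adjusted p = 0.000127; adjusted p = 0.174 with an estimated correlation), with 5 higher and 1 lower adjusted over the list alone. Resident-like macrophage genes were lower in 9 of 11 (median -1.39; camera adjusted p = 1.87e-07; adjusted p = 0.14 with an estimated correlation). Adjusted over the list alone 6 passed, among them FOLR2 (folate receptor beta, -1.44, SE 0.28), TIMD4 (-4.01, SE 0.85), SELENOP (-1.40, SE 0.40) and STAB1 (-1.39, SE 0.40), and 0 passed over all genes. MHC class II genes were negative in 10 of 10 (camera adjusted p = 0.00333; adjusted p = 0.433 with an estimated correlation), with 0 adjusted over the list alone. Complement genes were lower, 2 of 3 adjusted over the list alone, C2 at -1.32 (SE 0.25; camera adjusted p = 0.000247; adjusted p = 0.112 with an estimated correlation).

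**Figure D3:**
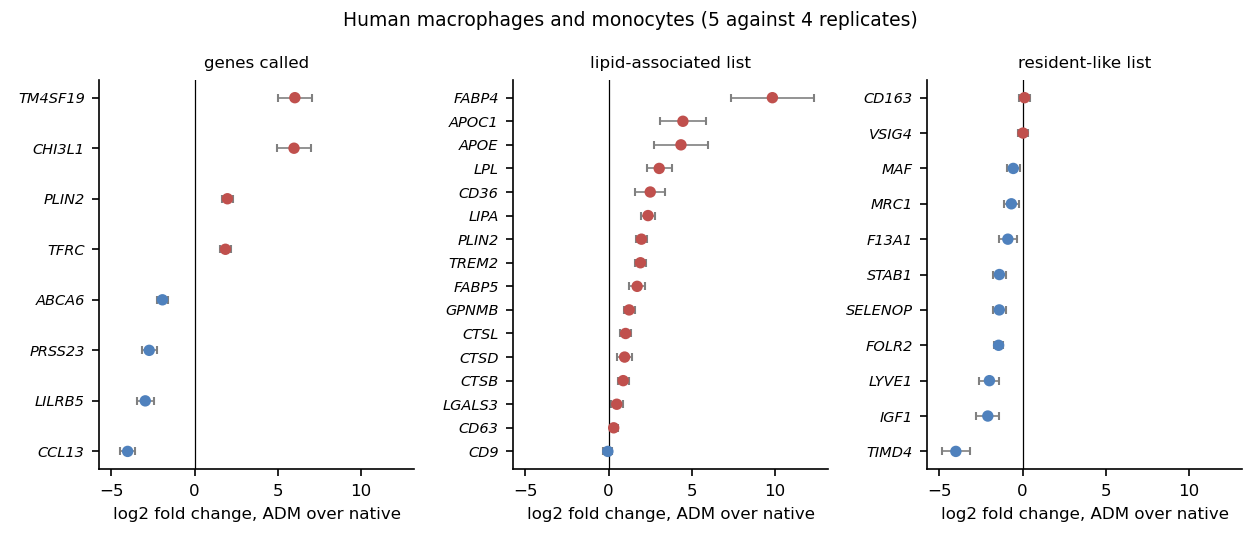
Log2 fold change (ADM over native, point ± SE) in human macrophages (n = 5 and 4) for the genes that passed, the lipid-associated list and the resident-like list. Among the genes that passed, values run from -4.02 for CCL13 to 6.03 for TM4SF19.

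Hypoxia and glycolysis genes were positive in 11 of 11 (camera adjusted p = 5.6e-06; adjusted p = 0.141 with an estimated correlation), with 2 adjusted over the list alone, HK2 (2.38, SE 0.62) and ALDOA (1.13, SE 0.30). Giant cell fusion genes were higher (camera adjusted p = 0.00833; adjusted p = 0.316 with an estimated correlation), and 2 of 8 passed when adjusted over the list alone, DCSTAMP (2.21, SE 0.49), needed for macrophage fusion, and MMP9 (3.29, SE 0.82). Over all macrophages MMP9 was 1670 CPM in ADM and 113 CPM in native capsule of set 2, but 3807 and 3432 CPM in set 1. Without hash doublets the set 1 direction turned, to 2951 CPM in ADM and 4272 CPM in native capsule. Matrix proteases were higher (camera adjusted p = 0.0322; adjusted p = 0.277 with an estimated correlation), with 2 adjusted over the list alone. Inflammatory cytokines were higher (camera adjusted p = 0.0226; adjusted p = 0.461 with an estimated correlation), with 3 higher, CCL7 (2.08) among them, and 1 lower, CCL8 (-2.55), adjusted over the list alone. TGF-beta response genes were lower (camera adjusted p = 0.0342, adjusted p = 0.403 with an estimated correlation), with 2 adjusted over the list alone. Mechanosensitive genes were lower as well (camera adjusted p = 0.0226, adjusted p = 0.271 with an estimated correlation), again with 2 adjusted over the list alone. Fibroblast markers were also lower in these macrophages, as given below. Whether doublets or free RNA of fibroblasts lowered the TGF-beta and mechanosensitive lists was not tested.

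Markers of other cell types moved with the condition in these macrophages. Fibroblast markers were lower in 7 of 7 (median -3.55; camera adjusted p = 3.64e-12; adjusted p = 0.121 with an estimated correlation), all 7 adjusted over the list alone, with COL1A1 at -4.03 (SE 0.71) and COL3A1 at -4.09 (SE 0.76). The collagen list, which shares 4 genes with them, was lower with 5 of 10 (camera adjusted p = 5.66e-08; adjusted p = 0.121 with an estimated correlation). Neutrophil markers were higher, 2 of 4 adjusted over the list alone, S100A8 (2.39, SE 0.57) and S100A9 (1.26, SE 0.33), which monocytes also express (camera adjusted p = 4.29e-05; adjusted p = 0.112 with an estimated correlation). In set 2, cluster 7, whose leading markers include SPP1, MMP9, TREM2, LPL and CHI3L1, held 55.2% of ADM and 3.36% of native macrophages, and cluster 13, led by CCL13 and LILRB5, held 10.5% and 76.5%. In set 1 cluster 7 went the other way, with 46.7% of 15 ADM and 69.2% of 13 native macrophages. Median UMIs per macrophage in set 2 were 9380 and 6085. Without set 1, 52 genes passed, 7 of them among the 8, and DESeq2 called 99 with all 8 among them. Leaving out single samples gave from 1 to 25 genes, with 1 gene without ADM sample 2 or 3 or native sample 2 of set 2.

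Human fibroblasts were compared to ask whether the mouse fibroblast differences had a counterpart. Set 1 had no native sample with 10 fibroblasts, so only set 2 informed the comparison (n = 4 and 5; 118 and 382 cells). No gene passed: 0 of 6794 by edgeR, with 294 at an unadjusted p under 0.05 (339.7 by chance) and 8 by DESeq2. A replicate block called 8, the 80% tag assignment 41, and leaving out set 1 called 0. MMP9, a gelatinase, had 56 UMIs in the hashed ADM samples and 0 in the native ones (edgeR adjusted p = 0.311). In pooled counts it was at least 48.9-fold higher against a floor of 3 counts over the group. This bound leaves out the spread between ADM samples, from 7.99 to 84.7 CPM. Macrophages held 97.4% of MMP9 UMIs in the set 2 ADM library, where a fibroblast had 0.262 (95% interval 0.203 to 0.332), a T or NK cell 0.159 (0.087 to 0.267) and a pericyte or smooth muscle cell 0.0488 (0.00591 to 0.176). Dendritic cells of that library had 0.321 (0.147 to 0.610). Their cluster also had 6 macrophage markers detected, so this RNA may be their own. The interval of T or NK cells overlapped that of fibroblasts, so free RNA and expression by fibroblasts were not told apart. CRTAC1, a cartilage matrix protein, had 0 UMIs in the hashed ADM samples and 1138 in the native ones (edgeR adjusted p = 0.530). In counts pooled over each group it was at least 145-fold lower. Native samples ran from 15.6 to 1391 CPM, a spread that this bound leaves out. CRTAC1 led the markers of fibroblast cluster 21, which held 4.45% of native and no ADM fibroblasts of set 2. CFD (complement factor D, -2.72, SE 0.56), F2R (the thrombin receptor, 1.73, SE 0.38) and TPM2 (a tropomyosin, 0.95, SE 0.21) had an edgeR adjusted p of 0.430, and ABI1 (0.96), FSTL3 (1.19), CCL26 (3.05) and ITIH5 (-1.24) from 0.530 to 0.561.

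SPP1 in human fibroblasts was 22.5 ± 16.8 against 3.28 ± 2.88 CPM (3.43, SE 0.83, edgeR adjusted p = 0.560, and between 3.42e-08 and 1.00 over the alternatives), above every native sample in 3 of 4 ADM samples. Over all set 2 ADM cells it was 0.395 UMIs per fibroblast (95% interval 0.321 to 0.479; median depth 15274 UMIs) and 0.330 per T or NK cell (0.221 to 0.473; median depth 2564 UMIs). In set 1 the whole-library level was 1.76 CPM in ADM and 4.57 CPM in native fibroblasts, the other direction from set 2 with 23.5 against 4.83 CPM. MMP9 likewise went the other way in set 1, at 0.88 against 3.43 CPM.

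Osteochondrogenic genes were negative in 5 of 5 (median -1.38; camera adjusted p = 3.54e-05; adjusted p = 0.108 with an estimated correlation). Adjusted over the list alone 3 passed, COMP (cartilage oligomeric matrix protein, -1.89, SE 0.48), ACAN (aggrecan, -3.83, SE 1.07) and ALPL (alkaline phosphatase, -1.38, SE 0.50). Complement genes were lower in 7 of 8 (camera adjusted p = 0.000577; adjusted p = 0.523 with an estimated correlation), with CFD adjusted over the list alone. Contractile genes were positive in 8 of 10 (camera adjusted p = 0.00267; adjusted p = 0.523 with an estimated correlation), with TPM2 adjusted over the list alone and MYL9 at 0.73 (SE 0.29). Of 3 giant cell fusion genes MMP9 passed adjusted over the list alone (camera adjusted p = 0.000979; adjusted p = 0.0995 with an estimated correlation; fry adjusted p = 0.0123), with the overlap with T and NK cells given above. The protease list, which shares 2 genes with it, was higher (camera adjusted p = 0.0279; adjusted p = 0.523 with an estimated correlation), again with 1 adjusted over the list alone. The collagen list was not called (camera adjusted p = 0.236), with POSTN at 1.498 (SE 0.52). Human counterparts of the mouse genes did not follow them: the 19 measured counterparts of the higher genes had a median of 0.00 (camera adjusted p = 0.751) and the 102 of the lower genes a median of 0.09 (camera adjusted p = 0.0997). Of the 102, 39 were ribosomal protein genes, 37 of them positive, and the other 63 had a median of -0.04 with 39 negative. In set 2, cluster 2, with COMP and ACAN among its leading markers, held 9.6% of ADM and 29.3% of native fibroblasts, cluster 1 held 48.8% and 11.5%, and cluster 14 held 26.4% and 46.6%.

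Shares of cells were compared in unsorted samples to ask whether ADM went with another cell make-up. Macrophages were 54.6% ± 5.45 of cells in mouse ADM samples and 31.2% ± 11.8 in native ones (SD, n = 2 and 3), a difference of 23.5 percentage points with an exact permutation p of 0.2, where 0.1 is the smallest this design allows, so no mouse class could pass. As a share of immune cells the difference was 0.06 points. Mouse T and NK cells were 10.1% against 2.45% (exact permutation p = 0.1), with 9.03% and 11.2% in the ADM samples and 1.65%, 1.85% and 3.86% in the native ones, and fibroblasts 11.98% against 40.2% (exact permutation p = 0.2); all 3 had a Benjamini-Hochberg adjusted p of 0.45 over the classes. Human macrophages were 26.8% ± 16.7 against 17.5% ± 19.96 (n = 7 and 8), a difference of 9.25 points (exact permutation p = 0.322 over 2520 permutations within sets, adjusted p = 0.936). The difference was 12.4 points in set 2 (exact permutation p = 0.381) and -1.50 in set 1 (exact permutation p = 0.9). The human difference was 20.4 points and passed with tags assigned within classes, and it was -1.96 as a share of immune cells. Shares depend on hashtags, which missed fibroblasts more often than macrophages.

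**Figure D4:**
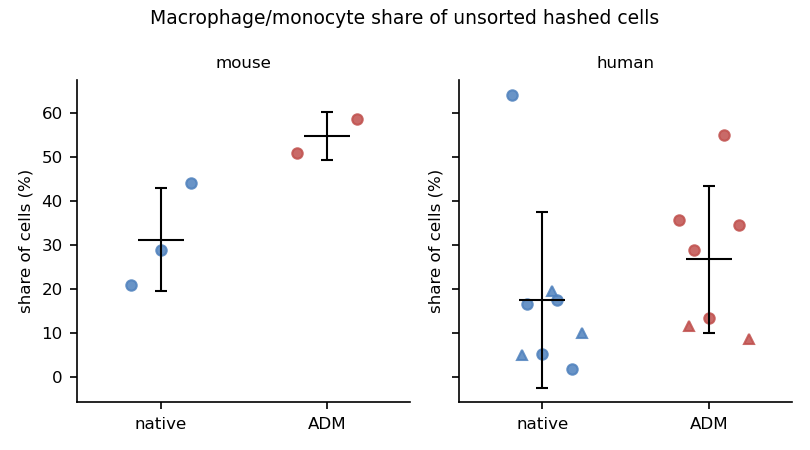
Macrophages as a percentage of the cells of each unsorted hashed sample, ADM against native, in mouse (n = 2 and 3) and human (n = 7 and 8), with mean ± SD. Human means were 26.8% next to ADM and 17.5% in native capsule, with overlapping samples.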

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

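The tests of sample splits, of handling through the stress genes and of sorting were chosen after the results were seen; the other tests of explanations were written down first.

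The 168 genes called in mouse fibroblasts were weighed first. Of the 35 ways to split the 8 samples, only 1, the real one, called as many, and the highest other called 4. A share of 1 in 35 is the smallest this test can give, so chance is unlikely but not excluded. A difference between the 2 libraries is not excluded either. Stress genes did not rise in macrophages of the same samples: their medians were -0.549 in unsorted and -0.0909 in Lin- macrophages (quartiles -0.268 to 0.059), against 0.939 and 0.657 in fibroblasts, which argues against handling that acts alike on both classes. Of the measured genes 83.8% kept their sign in Lin- and 75.7% in unsorted macrophages (all genes 56.4% and 52.5%). A difference between the libraries would give this. So could fibroblast RNA in macrophages from doublets or free RNA, which was not excluded. In unsorted fibroblasts 160 of 163 genes kept their sign (98.2%, all genes 66.8%). This argues against sorting as the whole cause as far as the Lin- label holds. Even so, 0 of these genes were called there by edgeR (1 of 8876 in all, 1241 at an unadjusted p under 0.05). Without cluster 12, whose share differed most, 23.2% of the genes were still called (39), fewer than in any of 10 random removals of as many cells (54 to 121), while 162 of 162 measured genes kept their sign and the median absolute fold change went from 0.775 to 0.688. A shift between fibroblast states may therefore carry part of the difference, next to a response within states, and this test cannot tell them apart.

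The second pattern was osteopontin mRNA in fibroblasts, which may be free RNA from macrophages. In the mouse ADM library a T or NK cell held 0.256 Spp1 UMIs (0.203 to 0.318), a B or plasma cell 1.08, a pericyte or smooth muscle cell 4.25 (3.81 to 4.73) and a fibroblast 7.62 (7.47 to 7.77). Without hash doublets T or NK cells, pericytes and fibroblasts had 0.211, 1.59 and 7.97. By UMIs per cell free RNA is therefore unlikely to account for all of the fibroblast level. Fibroblasts were also deeper, at a median of 8838 UMIs against 1529 in T or NK cells. By CPM fibroblasts had 701, above T or NK cells (111) but below neutrophils (749) and pericytes (858). In the native library pericytes held more UMIs per cell (3.25) than fibroblasts (1.87). By CPM native fibroblasts (217) lay below T or NK cells (329), so the ranking depends on the measure. In the human ADM library of set 2 a T or NK cell held 0.330 (0.221 to 0.473) and a fibroblast 0.395 (0.321 to 0.479), with 0.0976 (0.0266 to 0.250) in pericytes or smooth muscle cells, 0.60 (0.22 to 1.31) in endothelial and 1.18 (0.81 to 1.66) in dendritic cells. The dendritic cluster also had 6 macrophage markers detected, so its SPP1 RNA may be its own. Without it the classes still lie on both sides of fibroblasts, and the interval of T or NK cells overlaps that of fibroblasts. Free RNA and expression by human fibroblasts therefore cannot be told apart.

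The third pattern was the lower level of fibroblast markers in human ADM macrophages of set 2, a log2 ratio of native to ADM of 2.59 (SE 0.94; n = 4 and 3). It was 0.83 (SE 0.13) without the tenth of macrophages with most fibroblast marker UMIs: the geometric mean level in native samples went from 10.5 to 2.19 UMIs per cell and in ADM samples from 1.75 to 1.23. A few native cells therefore carried most of the difference, which is consistent with doublets with fibroblasts and not with an even change in all macrophages. Those cells were chosen on the same markers, so macrophages that make or take up these transcripts themselves remain open. In T and NK cells the ratio was 1.29 (SE 2.02), too uncertain to say whether free RNA adds to it.

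Further counts of genes were set against other splits. For human macrophages 2 of 70 splits called at least the 8 genes of the real one, which makes chance less likely but does not exclude it. The other is the same split with the 2 samples of set 1 exchanged, and it called 15, more than the real one. For human fibroblasts and for human T and NK cells the real count was 0, which all 100 drawn splits reach by construction, so the splits decide nothing there; the highest others were 10 and 8.

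Single samples lay far from the others of their group by Dixon's test in 18 of 151 groups, where chance gives about 1 in 20 groups (7.5). In human fibroblasts of set 2 these were ACAN at 7.86 CPM in an ADM sample (others 0) and 221 CPM in a native one (others 12.7 to 71.8), and TPM2 at 608 CPM in an ADM sample (466 to 480). In human ADM macrophages of set 2 they were CCL8 at 6.31 CPM (others 0), HK2 at 196 (43.5 to 69.5) and PRSS23 at 8.43 (11.96 to 12.6). A single sample of 21 macrophages gave LIPA at 1384 CPM (363 to 533), TM4SF19 at 223 (16.7 to 37.9), FOLR2 at 99.3 (217 to 234) and TFRC at 137 (219 to 230). In mouse ADM fibroblasts they were Abcc9 at 38.3 CPM (16.9 to 17.9), Dmkn at 1.16 (11.3 to 12.5), Lrrc15 at 207 (282 to 297) and Mmp14 at 1623 (1051 to 1092). A sample of 33 fibroblasts gave Pgk1 at 350.2 CPM (223 to 240) and Ptk7 at 81.9 (49.5 to 54.3), and a native sample gave Ndrg1 at 87.7 (125 to 126). The macrophage share was 64.1% in 1 native sample of human set 2 (others 1.92% to 17.6%).

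The ADM effect differed between human macrophages and fibroblasts of set 2 in 7 of 7583 genes (edgeR adjusted p under 0.05). The fit took the classes as independent samples, although some hashed samples gave both, so this pairing was ignored. The macrophage effect minus the fibroblast effect was -4.42 for TGFB1I1, -3.65 for KANK2, -4.04 for COL1A1, -4.08 for COL6A3, 4.73 for RAI14, 3.08 for TSC22D1 and 4.25 for CSF1. COL1A1 and COL6A3 belong to the fibroblast markers, and doublets or free RNA may lower them in macrophages as described above (0.83 against 2.59). TGFB1I1 and KANK2 had the same pattern, at -3.94 and -3.49 in macrophages against 0.38 and 0.05 in fibroblasts. Whether doublets or free RNA lower these as well was not tested. For SPP1 the difference was 0.91 (SE 1.73, edgeR adjusted p = 0.979).

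Immune classes made up 58.3% (95% interval 55.6 to 61.1) of cells in the Lin- samples of the mouse ADM library, 55.8% (53.3 to 58.2) in the native one, and 62.1% (48.4 to 74.5) and 79.2% (68.0 to 87.8) in ADM and native samples of human set 1, although the mouse sort is stated to remove CD45-positive cells. Unsorted samples held 78.9% and 47.9% (45.5 to 50.3) in the mouse ADM and native libraries. These intervals cover counting error only. By hashed sample the native values overlapped, from 41.5% to 62.7% in Lin- and from 37.2% to 58.9% in unsorted samples. The mouse ADM values did not, with 43.75% to 67.4% in Lin- and 77.7% to 79.9% in unsorted samples. How well the Lin- label separates the samples was not settled.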

How the results depend on the processing

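The hashtag assignment within each class and the removal of single human samples were chosen after the results were seen. Of 2164 values for the 110 named genes under the alternatives, 1799 kept direction and side of the threshold, 175 became weaker, 186 stronger and 4 reversed. All 4 reversed with tags assigned at 80% or more: Grem1 (-0.10), Col7a1 (-0.42), Ptk7 (-0.12) and Pgk1 (-0.14). Only a gene that passed in its main fit could become weaker, and the values kept include genes that stayed above the threshold throughout. The weaker values were 105 in mouse fibroblasts and 70 in human macrophages, where only 8 genes had passed. The pooled count therefore overstates how stable the genes that passed were. The cause was not tested for any change below. Mouse fibroblasts (168 genes) gave 289 without a count filter, 269 with the block and 718 with unsorted samples added, and 41 to 188 without single samples (ADM 3: 94, ADM 4: 80, native 3: 50, native 4: 41). Spp1 there passed without the filter (1.66) and with unsorted samples (1.67) and was 0.60 with the 80% assignment, with 1.24 to 2.00 without single samples. Mouse macrophages (0 genes) gave 27 by DESeq2, 1 with the 80% assignment, 1 with the assignment within classes, and 0 to 9 without single samples (ADM 5: 9, native 6: 1). Spp1 there reversed with the block (0.28) and ran from -0.84 to 0.27 without single samples (native 5: 0.27). Human fibroblasts (0 genes) gave 8 by DESeq2, 113 without the filter, 41 with the 80% assignment, 1 with at least 30 cells, 8 with the block, and 0 to 3 without single samples (native 3 of set 2: 3). SPP1 there passed without the filter (3.48) and with the 80% assignment (6.06), with 2.52 to 4.17 without single samples. Human macrophages (8 genes, 4 higher and 4 lower) gave 99 by DESeq2 (62 and 37), 24 with library sizes (7 and 17), 310 without the filter, 27 with stricter cell filters, 16 with the 80% assignment, 154 and 54 at Leiden resolutions 0.5 and 2, 1 without Scrublet doublets, 52 with at least 30 cells, 41 with the block, 79 with the assignment within classes, 0 without a set term, 52 without set 1, and 1 to 25 without single samples (set 1 ADM 5: 22, native 5: 25; set 2 ADM 2: 1, ADM 3: 1, ADM 5: 3, ADM 6: 20, native 2: 1, native 3: 2). SPP1 there passed by DESeq2 (3.65), without the filter (3.73), at resolution 0.5 (4.27) and within classes (4.65), with 3.07 to 5.50 without single samples. The 37 list calls became 0 with an estimated correlation and 38 with the block. The human macrophage share difference reversed as a share of immune cells (-1.96) and without set 2 (-1.50), passed with the assignment within classes (20.4), and ran from -1.50 to 15.9 without single samples or a set (without native 2 of set 2: 15.9). The mouse share difference nearly vanished as a share of immune cells (0.06), otherwise reached up to 24.96, and from 18.3 to 29.9 without single samples. Leaving out set 2 gave no usable design for the human gene tests, which were not run. Samples with the same number in ADM and native libraries correlated from -0.23 to 0.262, not all over 0.1, so numbers were not taken as pairs. Samples held 12 to 139 human fibroblasts and 10 to 202 human macrophages.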

Other observations

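The comparisons of Lin- macrophages and of unsorted fibroblasts here were added after the results were seen.

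Macrophages were also present in the Lin- mouse samples, 430 ADM and 501 native cells in 4 and 4 hashed samples. Spp1 was 0.97 there (SE 0.51, edgeR adjusted p = 0.760), against -0.37 in unsorted macrophages. Of 4352 genes 2 passed (edgeR quasi-likelihood test). The median of the stress genes was -0.0909, with 9 of 14 negative. Fibroblasts of the unsorted mouse samples (142 and 590 cells, n = 2 and 3) had Spp1 at 1.67 (SE 0.66, edgeR adjusted p = 0.312).

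Mouse dendritic cells (108 ADM and 72 native cells, n = 2 and 2) had 0 of 3719 genes pass by edgeR, with 399 at an unadjusted p under 0.05 (186 by chance). The smallest p were those of S100a4 (-1.47, SE 0.16, edgeR adjusted p = 0.0614) and of the chemokine Ccl3 (-2.88, SE 0.38, edgeR adjusted p = 0.0678). Mouse neutrophils (48 and 87 cells, n = 2 and 2) had 0 of 532, with 29 at an unadjusted p under 0.05 (26.6 by chance). Human T and NK cells (140 and 134 cells, n = 6 and 6) had 0 of 1019, with 49 (50.95 by chance), and CCL4 at 1.5 (SE 0.38, edgeR adjusted p = 0.542). DESeq2 was not run on these classes.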
